A study of Triticum aestivum with 6 samples.

How the data were processed

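The series compared oxidised mRNA of dry dormant wheat seeds (3 arrays) with that of dry seeds after-ripened for 10 months at room temperature (3 arrays). Per the labels' protocols, oxidised mRNA was isolated with a monoclonal antibody against 8-hydroxydeoxyguanosine and hybridised as biotinylated cRNA to the Affymetrix wheat GeneChip. The deposited values were log2 signals, 1 per probe set and array, made with RMA per the submitters' processing notes. The software, its version and its settings were not given in the sources used here. The log2 scale was checked on the values, whose quantiles were nearly the same on all 6 arrays. RMA brings all arrays to a common distribution, so a shift shared by all transcripts cannot be seen. Array number limits the precision. The p-values of single probe sets rest only in part on the spread between 3 samples per group. Limma draws each variance toward that of all probe sets, here with 7.29 prior against 4 residual degrees of freedom. The labels call these samples biological replicates.

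Names came from the platform annotation given for the array, which is old, and were extended through gene identifiers with the synonyms of a gene table of the assembly IWGSC CS RefSeq v2.1, used for names only. Of the probe sets, 1273 had 1 gene symbol, none had several and 59906 of those tested had none. Of 771 symbols, 770 were found in the gene table. A readable name, meaning a symbol other than a numbered placeholder or a synonym, was available for 200 probe sets of 102 genes. Numbered identifiers are printed beside the synonym. The deposited values name no genome build, so no coordinates are given.

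The 111 Affymetrix control probe sets were left out of the tests. For the other 61179, a linear model of the log2 values with group as its only term was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, after-ripened minus dormant. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05, and counts at a change of at least 2-fold were also taken. All adjusted p-values of single probe sets are from limma. Replicate numbers did not serve as a block in this fit. The model was tested on simulated data with the real means and limma's moderated variances, 3 arrays against 3 and 61179 probe sets. It recovered 82% of 50 probe sets changed by 0.5 on the log2 scale and 100% of 50 each at 1, 2 and 3, with 14 unchanged probe sets among 205 calls. On simulated lists, camera called 20 of 20 shifted lists and 0 of 200 unshifted lists, of which 10 had an unadjusted p under 0.05. Probe sets were simulated independently of one another, so this check says nothing about lists whose genes are correlated. In the real data, the correlation estimated for the prolamin list was 0.46.

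Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 5 probe sets. Camera with an estimated correlation and fry, a self-contained test that does not compare a list with other genes, were run beside it. Before the data were examined, 23 lists were written as name patterns. With no gene descriptions in the tables, the patterns were matched to symbols and synonyms, which left 7 lists empty, 7 too small and 9 tested. The pattern for organelle-encoded genes also took in nuclear genes, so its result is not read as organelle transcripts. After the names but before any value of a named probe set had been seen, 12 extended lists were drawn up from the synonyms, 10 of which were large enough to test. Counts adjusted over the list alone use the same limma p-values. A list of embryo genes was chosen after values had been seen.

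Genes to be named were chosen by a rule fixed before the data were examined. In each direction it took the 12 probe sets with a readable name, an adjusted p under 0.05 and no overlap between groups that had the largest change. A direction with fewer was filled in order of unadjusted p under 0.05, and these are given as not past the threshold. In each gene list the 2 members of smallest unadjusted p in each direction were added. A gene with several chosen probe sets was named by the probe set with the highest mean. At most 2 probe sets without a name were given in each direction. Names outside the rule are marked in the text as chosen after their values were seen. Members given as a gene's further probe sets illustrate disagreement within a gene.

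Alternatives fixed before the data were examined were the replicate number as a block, a repeated quantile normalisation, subtraction of array medians and filters at the 25th and 50th percentile of mean signal. Others were an intensity trend with a robust prior, array weights, variances of each probe set alone and leaving out each array in turn. Further ones were an unadjusted p under 0.05 with a 2-fold change, an adjusted p under 0.1, limma's treat against 1.5-fold, camera with an estimated correlation, fry and 1 probe set per gene. Alternatives chosen after seeing the data were the mean of 12 spiked poly-A control probe sets as a covariate and the restriction to probe sets with the plain suffix _at. The extended lists were also an addition, made at the stage stated above. A planned pseudocount was not needed, because the values were already log2. Array quality was described from poly-A and hybridisation controls, 18S rRNA and 3′ to middle or 5′ ratios, compared by two-sided exact permutation tests.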

Results

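Oxidised mRNA was compared between dry dormant and dry after-ripened seeds of bread wheat, genotype AC Domain. After-ripening is the loss of seed dormancy during dry storage. The after-ripened seeds had been kept for 10 months at room temperature, and the dormant seeds were kept frozen so that they stayed dormant. RNA carrying oxidised guanine was taken down with an antibody against 8-hydroxydeoxyguanosine, labelled as biotinylated cRNA and hybridised to the Affymetrix wheat GeneChip. Each group had 3 arrays, which the labels call biological replicates. The values were log2 RMA signals, with 61179 probe sets tested and 111 array controls left out. Array medians lay between 5.25 and 5.31. Correlations between arrays were taken over all probe sets, array controls included. They were 0.996 to 0.997 within the dormant group, 0.997 within the after-ripened group and 0.993 to 0.996 between the groups. The first principal component held 42.6% of the variance and separated the groups, with scores of -42.3, -12.0 and -9.51 for the dormant arrays and 17.3 to 23.7 for the after-ripened arrays. The score of -42.3 belonged to dormant replicate 2. No array of unselected mRNA was used here, so each value is the signal of a transcript in the oxidised mRNA pool.

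The comparison asked which transcripts differed in the oxidised mRNA of dry seeds once dormancy had been lost by storage. Of 11 probe sets for gliadins and glutenins, the storage proteins of the starchy endosperm, 7 were higher in after-ripened seeds, as were 7 of 12 for amylase, protease and xylanase inhibitors of the grain in an extended list. Of the 5 inhibitor probe sets in the list fixed before the data were examined, 1 was higher, and that list was not called (camera, adjusted p = 0.202). Neither the prolamin list nor the extended inhibitor list was called when the correlation between genes was estimated (camera, adjusted p = 0.141 and 0.158 with an estimated correlation). The alpha-gliadin gene Gli-8 (LOC543211) rose from 12.19 ± 0.29 to 14.23 ± 0.12 (log2 signal, SD, n = 3), and the monomeric alpha-amylase inhibitor gene WMAI-1 (LOC542981) rose from 10.42 ± 0.18 to 12.42 ± 0.20. A small heat shock protein gene, hsp16.9A, also rose, at a low signal. Among genes with a readable name, rbcl, for the large subunit of Rubisco, was the only gene with a lower signal past the threshold. It was lower on 2 of its 28 probe sets, most of which hybridised weakly. These 2 carried a suffix for probe sets that can be shared between transcripts. Lists of late embryogenesis abundant, redox, histone, cytoskeleton and translation genes held no probe set past the threshold.

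**Figure D1:**
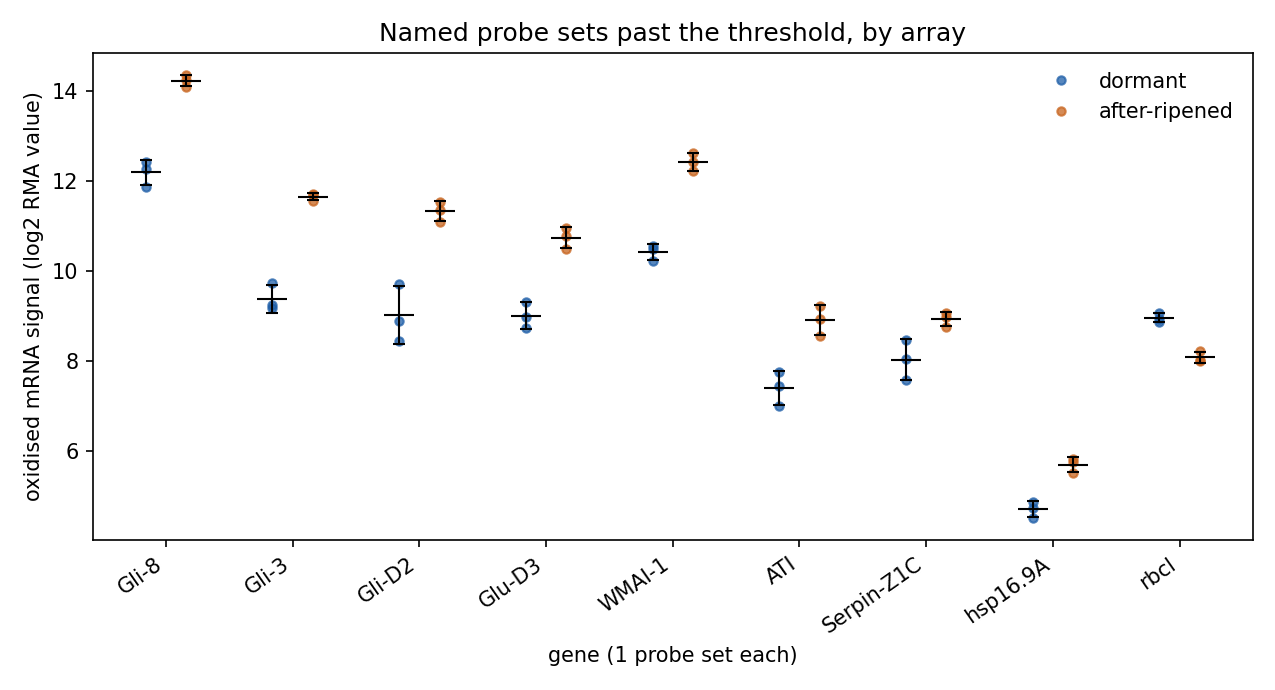
Oxidised mRNA signal (log2 RMA value, vertical axis) of 9 genes past the threshold (horizontal axis, 1 probe set each) in dormant and after-ripened seeds. Points are arrays, the long bars are means and the whiskers are SD (n = 3). The 3 arrays of each group lay apart from those of the other group for every gene shown, with rbcl lower and the other 8 genes higher in after-ripened seeds.

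Of the prolamin list fixed before the data were examined, which held 11 probe sets of 6 genes, 7 were higher in after-ripened seeds over all probe sets tested and 9 when adjusted over the list alone. None was lower by either count. The median log2 change was 1.55, and the list was called by limma's camera with a preset correlation (adjusted p = 1.13e-18). The list was not called when the correlation was estimated from the data (adjusted p = 0.141 with an estimated correlation). The self-contained test fry gave an adjusted p of 0.0132. The largest changes of the list in limma's fit belonged to 3 alpha-gliadin genes. Gli-3 (LOC543210) rose by 2.27 ± 0.14 on the log2 scale (SE, adjusted p = 5.92e-05), Gli-8 by 2.04 ± 0.13 (adjusted p = 5.92e-05) and Gli-D2 (LOC543212) by 2.32 ± 0.25 (adjusted p = 0.0013). The other called probe set of Gli-D2 rose by 1.81 ± 0.15. A further alpha-gliadin gene, Gli-B2-11 (LOC543385), mentioned after its values were seen, had a log2 change of 0.63 ± 0.14, which did not pass (limma, adjusted p = 0.0587). Its probe set hybridised weakly (mean 3.74). The low-molecular-weight glutenin gene Glu-D3 (LOC543213) rose by 1.73 ± 0.15 and, on another probe set, by 1.55 ± 0.18, while its weakly hybridising remaining probe set had a log2 change of 0.03 ± 0.12, not past the threshold. The 3 probe sets of a gamma-gliadin gene (LOC543214) disagreed. The one chosen by the naming rule had a log2 change of -0.02 ± 0.13 (limma, adjusted p = 0.961), but it hybridised weakly (mean 5.18). The others were given after their values were seen. One, with a mean of 11.69, rose by 1.27 ± 0.16 (limma, adjusted p = 0.00302). The other, with a mean of 7.20, had a log2 change of 0.53 ± 0.19, which did not pass (limma, adjusted p = 0.231).

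An extended prolamin list, drawn up from gene synonyms before any value of a named probe set was seen, added the avenin-like genes. It held 17 probe sets of 8 genes, of which 9 were higher over all probe sets tested. When adjusted over the list alone, 12 were higher and 1 was lower. The median log2 change was 0.98 (limma's camera, adjusted p = 1.48e-18; adjusted p = 0.158 with an estimated correlation). The 4 probe sets of avenin-like b (LOC100125692), a gluten-associated storage protein, did not move together. The naming rule chose 2 of them. The one with the higher mean, by which the gene is named, had a log2 change of -0.21 ± 0.08 and was not past the threshold over all probe sets (limma, adjusted p = 0.274). The other rose by 1.64 ± 0.21 (limma, adjusted p = 0.00452). A further one, picked after its values were seen, rose by 0.98 ± 0.16 (limma, adjusted p = 0.0166). The remaining probe set had a log2 change of 0.31 ± 0.22, not past the threshold. The call at 0.98 was lost without dormant replicate 1 or 3 and without after-ripened replicate 2 or 3, where limma's adjusted p was 0.0512 to 0.0778.

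The extended inhibitor list held 12 probe sets of 8 genes, of which 7 were higher over all probe sets tested and 8 when adjusted over the list alone. None was lower, and the 5 that did not pass over all tested were both probe sets of the xylanase inhibitor XIP-I, those of Serpin-Z2A and Serpin-Z2B, and 1 of the serpin gene WSZ1b. XIP-I and Serpin-Z2B were named after their values were seen. XIP-I read 14.3 in both groups, with log2 changes of 0.03 ± 0.08 and 0.02 ± 0.09. Whether a rise from so high a signal can still be seen was not tested, though Gli-8 reached 14.23 in after-ripened seeds. The list's median log2 change was 0.86 (limma's camera, adjusted p = 1.37e-13; adjusted p = 0.158 with an estimated correlation; fry, adjusted p = 0.0206). The inhibitor list fixed before the data were examined held only 5 of these probe sets. It was not called (median log2 change 0.087, camera, adjusted p = 0.202, and 0.953 with an estimated correlation). Without dormant replicate 2 it was called at the preset correlation (median 0.19, camera, adjusted p = 0.000663), and an estimated correlation was not run there. It held 1 higher probe set over all tested and 1 when adjusted over the list alone. WMAI-1 rose by 2.0 ± 0.12 (SE, limma, adjusted p = 5.92e-05). An alpha-amylase/trypsin inhibitor gene (LOC543286) rose by 1.5 ± 0.19 on the probe set of its highest mean, and its other 2 called probe sets rose by 1.83 ± 0.18 and 1.84 ± 0.20. A further gene of this family (LOC543281) rose by 1.47 ± 0.17. Serpin-Z1C (LOC542985), a serine protease inhibitor of the grain, rose by 0.91 ± 0.18 (limma, adjusted p = 0.0429). The serpin gene WSZ1b (LOC100037548), named after its values were seen, rose by 0.82 ± 0.15 (limma, adjusted p = 0.0283), and its other probe set had a log2 change of 0.66 ± 0.19, which did not pass (limma, adjusted p = 0.131). Both serpin calls were lost without dormant replicate 1, dormant replicate 3 or any 1 after-ripened replicate, where limma's adjusted p was 0.0852 to 0.144 for Serpin-Z1C and 0.0758 to 0.113 for WSZ1b. Gliadins, glutenins and these inhibitors are large gene families, and many of the probe sets detect several members, so the member behind a signal is uncertain.

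Some control measures moved alongside these groups of genes, though with so few arrays none could pass 0.05. For the control gene G6PDH, the 3′ to middle ratio was higher in after-ripened seeds by only 0.031 (exact permutation test, two-sided, p = 0.7). Its 3′ to 5′ ratio was higher there by 0.14 and the hybridisation controls by 0.097 (exact permutation p = 0.3 for each). The ratio of 3′ to middle probe sets of sucrose synthase was higher in after-ripened seeds by 0.29 on the log2 scale (exact permutation test, two-sided, p = 0.1, n = 3 per group), and the 18S rRNA signal was lower, with a difference of -0.09 (exact permutation p = 0.1). The spiked poly-A controls read 6.03 ± 0.43 in dormant and 5.67 ± 0.11 in after-ripened seeds (SD, exact permutation p = 0.3). With the level of these controls as a covariate, chosen after seeing the data, 226 of all probe sets tested differed in limma's fit. The median log2 changes under this covariate were 1.82 for the fixed prolamin list and 1.15 for the extended inhibitor list, and both lists were called by camera at its preset correlation (adjusted p = 8.28e-27 and 2.07e-21). Camera with an estimated correlation was not run with this covariate. Without the covariate it called neither list (adjusted p = 0.141 and 0.158). With 3 arrays against 3, the smallest p the exact permutation test can give is 0.1.

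**Figure D2:**
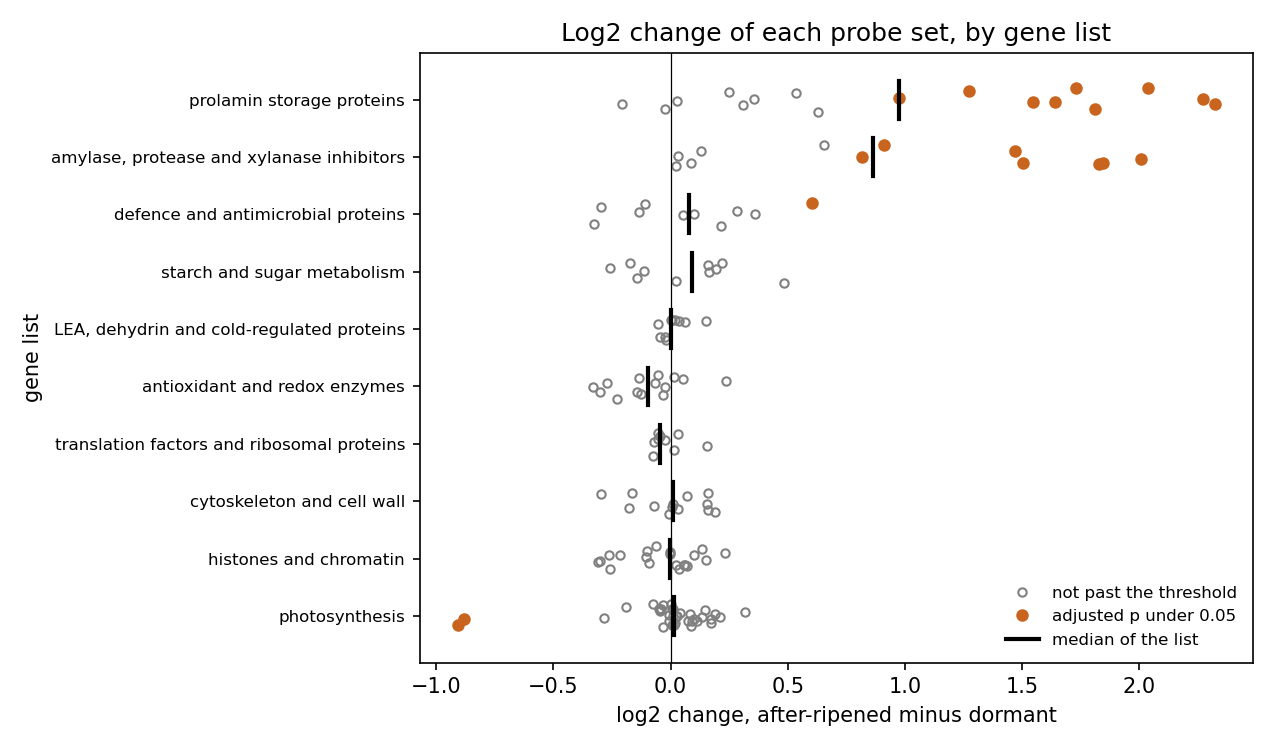
Log2 change from dormant to after-ripened seeds (horizontal axis) of each probe set in 10 gene lists (vertical axis, extended lists). Filled points passed an adjusted p of 0.05, open points did not, and the black bars are list medians, 0.98 for prolamins and 0.86 for inhibitors. Points are spread vertically at random within a list.

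Among other named genes, hsp16.9A (LOC543277), a small heat shock protein that keeps other proteins from aggregating, rose by 0.99 ± 0.11 (SE, limma, adjusted p = 0.002). It read 4.70 in dormant and 5.69 in after-ripened seeds, a low signal at which the size of a change is uncertain. The other gene of the heat shock list, FKBP70 (LOC543314), had a log2 change of -0.09 ± 0.08, not past the threshold. TTHV, a thionin gene of the defence list, rose by 0.60 ± 0.12 (limma, adjusted p = 0.0475). That call was lost without dormant replicate 1, dormant replicate 3 or any 1 after-ripened replicate (limma, adjusted p 0.081 to 0.164). The related thionin gene Pur-A1 (LOC543413) had log2 changes of 0.36 ± 0.12 and 0.28 ± 0.13, neither past the threshold. DMAS1 (LOC100037594), which makes the iron-binding phytosiderophore deoxymugineic acid, was named after its values were seen. It rose by 0.72 ± 0.11 and 0.61 ± 0.10 on 2 probe sets (limma, adjusted p = 0.00944 and 0.0135). Its remaining probe set, the one with the highest mean, had a log2 change of 0.31 ± 0.10, which did not pass (limma, adjusted p = 0.165). The call at 0.72 was lost without dormant replicate 3 (limma, adjusted p = 0.0544). The call at 0.61 was lost without dormant replicate 3 and without any 1 after-ripened replicate (limma, adjusted p 0.0516 to 0.0685). Genes of starch synthesis did not pass the threshold: the granule-bound starch synthase gene waxy (LOC543395) had a log2 change of 0.48 ± 0.12 (limma, adjusted p = 0.0864), and AGP-S (LOC543299), the small subunit of ADP-glucose pyrophosphorylase, had -0.26 ± 0.09 (limma, adjusted p = 0.237). Over the extended starch and sugar list of 10 probe sets, none was past the threshold over all tested and 1, waxy, was higher when adjusted over the list alone.

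The lower signals had few names. The 2 lower rbcl probe sets had log2 changes of -0.88 ± 0.10 and -0.91 ± 0.09 (SE, limma, adjusted p = 0.00151 and 0.0011). The other 26 probe sets of rbcl did not pass, and the list's median log2 change was 0.02. The most positive of them had a log2 change of 0.32 ± 0.11 (limma, adjusted p = 0.23). Most of these 26 had means under 5.29, the median level of all probe sets, so the list's median says little about rbcl. Those with higher signals, with means of 7.02 and 8.24, had log2 changes of -0.075 and -0.052. The means of the lower ones were 8.43 and 8.51. The lower ones carried the suffix _x_at, of probe sets that can be shared between transcripts, while those at 7.02 and 8.24 had the plain suffix _at. Which transcript lay behind the fall is therefore uncertain. The next lower named genes by unadjusted p were not past the threshold. They were PCS1, for phytochelatin synthase (-0.55 ± 0.16), the ubiquitin-conjugating enzyme gene UBC1 (-0.29 ± 0.09; its other 2 probe sets -0.05 and -0.12) and OEE1, for a protein of the oxygen-evolving complex (-0.28 ± 0.09). The chromatin gene Hmgb3, for a high-mobility-group protein (-0.26 ± 0.09, and -0.26 on its other probe set), followed, as did HGGT, an enzyme of tocotrienol synthesis (-0.34 ± 0.12). Their adjusted p-values in limma's fit were 0.142, 0.159, 0.193, 0.216 and 0.232. For the histone gene wcH2B-8, the 3 probe sets chosen by the rule went both ways, with 0.15 ± 0.09 on the one of highest mean and 0.23 ± 0.11 and -0.30 ± 0.11 on the others, none past the threshold. By unadjusted p, its probe set at -0.30 ranked between OEE1 and Hmgb3 (limma, adjusted p = 0.209).

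The remaining lists were not called. Of the 9 tested lists fixed before the data were examined, the 8 other than prolamins had medians from -0.11 to 0.087 and camera adjusted p-values from 0.202 to 0.935. Markers of the starchy endosperm fixed in advance, Glu-D3 and waxy, had 4 probe sets, too few for camera. Of these, 2 were higher over all tested and 3 when adjusted over the list alone (median log2 change 1.02). The aleurone marker peroxidase PER1 had 2 probe sets with a median of -0.088, neither past the threshold by either count. Over the extended lists, medians were 0.0025 for 10 probe sets of late embryogenesis abundant and cold-regulated proteins and -0.096 for 14 of antioxidant and redox enzymes. They were -0.0012 for 20 probe sets of histones and chromatin, 0.011 for 13 of cytoskeleton and cell wall genes and -0.044 for 9 of translation genes. No member of these 5 lists was past the threshold over all tested, and none was when adjusted over the list alone. In the first of these lists, 5 probe sets of the Em genes read 14.7 to 15.0, near the array maximum, where a change could hardly be seen. Camera's adjusted p-values for the 5 lists were 0.985, 0.191, 0.801, 0.985 and 0.985. The photosynthesis list of 36 probe sets (median 0.012, camera's adjusted p = 0.985) held the 2 lower rbcl probe sets over all tested and the same number when adjusted over the list alone. Most of its probe sets were of rbcl and hybridised weakly. The defence list of 10 probe sets (median 0.077, camera's adjusted p = 0.801) held the higher TTHV probe set by both counts.

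Over the whole array, 651 of 61179 probe sets differed in limma's fit at a Benjamini-Hochberg adjusted p under 0.05, 405 higher and 246 lower in after-ripened seeds. Of these, 80 were higher and 39 lower by at least 2-fold. The groups did not overlap for 19.5% of all probe sets, where chance gives 10%. The median log2 change over all probe sets was 0.0057. Only 22 of the differing probe sets had a readable gene name, 20 higher, from 14 genes, and 2 lower. A further 26 had a placeholder symbol and 603 had no symbol, so most of the differing transcripts could not be named. The largest changes belonged to probe sets without a symbol. The 2 largest rises were 3.49 ± 0.45 and 2.78 ± 0.26 on the log2 scale (SE, limma, adjusted p = 0.00403 and 0.000673), with a dormant mean of 3.84 for the smaller of them, a low signal at which the size of a change is uncertain. The 2 largest falls had log2 changes of -2.22 ± 0.18 and -1.80 ± 0.20 (SE, limma, adjusted p = 0.00021 and 0.00151). The count depended on the arrays used: it was 244 without dormant replicate 3, 222 without after-ripened replicate 1, 250 without after-ripened replicate 2 and 381 without after-ripened replicate 3. Variances estimated for each probe set alone gave 0 probe sets at an adjusted p under 0.05, with 6813 at an unadjusted p under 0.05 against 8620 in limma's fit.

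**Figure D3:**
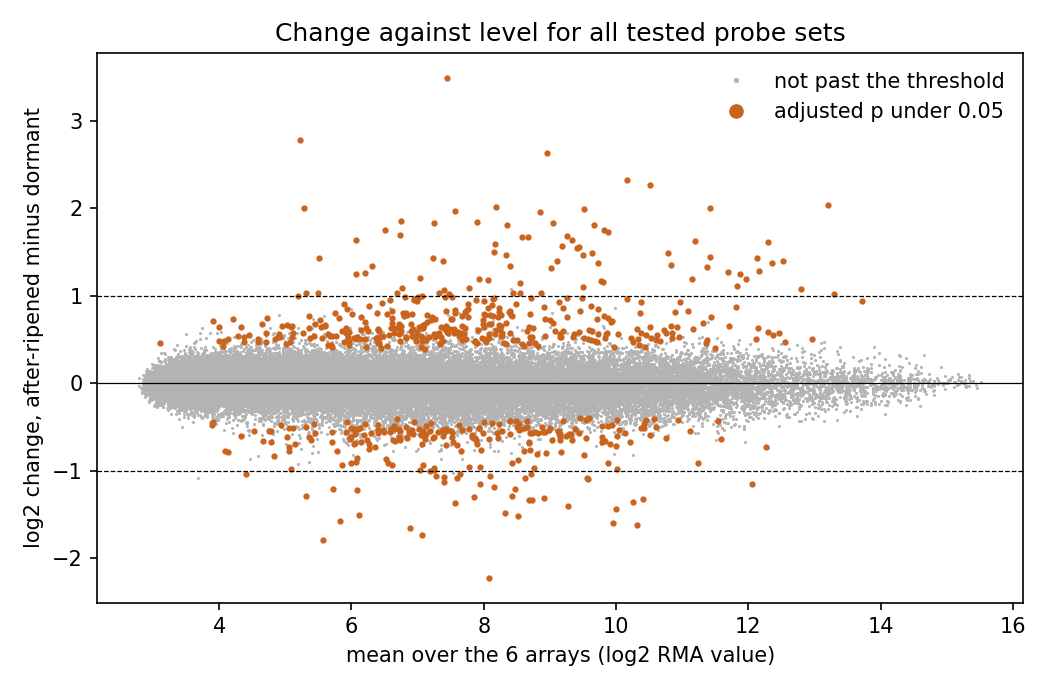
Log2 change from dormant to after-ripened seeds (vertical axis) against the mean log2 RMA value over the 6 arrays (horizontal axis) for 61179 probe sets. Coloured points are the 651 probe sets with an adjusted p under 0.05, and the dashed lines mark 2-fold changes. Probe sets past the threshold lay at higher signals than most, with median levels of 7.74 (higher) and 7.65 (lower) against 5.29 for all.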

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

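The covariate of spiked poly-A controls and the restriction to plain _at probe sets were chosen after seeing the data, and the extended lists after seeing the gene names but before any value of a named probe set. The 651 differing probe sets in limma's fit (405 higher, 246 lower) became 996 (455 lower) with the filter at the 50th percentile and 1048 (473 lower) with an intensity trend and robust prior. The count was 1682 (847 higher, 835 lower) at an adjusted p under 0.1 and 122 (81 higher, 41 lower) at an unadjusted p under 0.05 with a 2-fold change. It was 34 (30 higher, 4 lower, all 34 at least 2-fold) with treat against 1.5-fold. With the poly-A covariate it was 226 (172 higher, 54 lower), of which 198 were among the 651. Variances of each probe set alone gave 0 in either direction and 0 at 2-fold, with a smallest adjusted p of 0.216 and 6813 at an unadjusted p under 0.05. Plain _at probe sets held 67 of at least 2-fold against 119. Leaving out 1 array gave 222 to 662 probe sets, 140 to 353 higher and 58 to 310 lower, and 108 to 134 of at least 2-fold. The higher share of the calls, 62.2% with all arrays, was 54.3% with the 50th percentile filter, 54.9% with trend and robust prior and 76.1% with the poly-A covariate. Scaling hardly moved it (63.4% after quantile normalisation again, 59.5% after subtraction of medians). Filters also change the number of probe sets tested; the cause was not tested otherwise.

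The number of lists called, 1 with all arrays, was 2 with the 50th percentile filter, 2 with the poly-A covariate, 2 over the extended lists and 0 with an estimated correlation. With plain _at probe sets it was 0, since the prolamin list then held only 4 probe sets and was not tested. Leaving out 1 array gave 1 to 2 lists, 2 without dormant replicate 2. The list gained there and with the poly-A covariate was the fixed inhibitor list, with medians of 0.19 and 0.18 (camera at the preset correlation, adjusted p = 0.000663 and 0.00529). Over all arrays left out in turn, its median was 0.0125 to 0.19 and camera's adjusted p 0.000663 to 0.807. The extended prolamin list had a median of 0.61 over plain _at probe sets against 0.98 over all its probe sets. Median log2 changes near 0 changed sign. The organelle pattern list had -0.075 with the 50th percentile filter, under which it was called. With 1 array left out, its median ran from -0.0098 to 0.045, that of late embryogenesis abundant proteins from -0.054 to 0.054, of redox enzymes from -0.093 to 0.032 and of photosynthesis from -0.014 to 0.057, each turning without after-ripened replicate 2.

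With the replicate number as a block, 584 probe sets differed, 490 of them among the 651, and 1 list was called. Deviations of same-numbered replicates correlated at -0.049, -0.057 and -0.175, too few values to settle pairing. The block ended no named call. All 26 called probe sets considered here (22 with readable names, 4 without symbols) kept their direction, largely fixed since groups did not overlap. Their calls held for 26 after quantile normalisation again and with array weights, 24 after subtraction of medians (lost for Serpin-Z1C and TTHV), 23 with the poly-A covariate (lost for TTHV and both DMAS1 probe sets, whose log2 changes were 0.73, 0.72 and 0.56 against 0.60, 0.72 and 0.61 without it), 20 to 26 with 1 array left out, 11 with treat and 0 with variances of each probe set alone. Signals near the low end of the arrays limit what can be seen for weakly hybridising probe sets.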

Other observations

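The test of a larger endosperm share, the count of splits for probe sets and the embryo list were chosen only after the results they bear on were seen. No embryo transcript considered passed the threshold, in a set that could show little. The Em genes, for late embryogenesis abundant proteins of the mature embryo, and the wheat germ agglutinin gene WGA2 were represented by 6 probe sets, none past the threshold over all tested and none when adjusted over the list alone. Their median log2 change was -0.0087, but the 5 Em probe sets read 14.7 to 15.0, near the top of the arrays, so a change in them could hardly be seen. WGA2 itself read 13.60 ± 0.33 in dormant and 13.27 ± 0.05 in after-ripened seeds (SD, n = 3), with a limma adjusted p of 0.311.

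Prolamin and inhibitor transcripts had a median log2 change of 0.91 over the 29 probe sets of both extended lists, with 27 above 0. A larger share of starchy endosperm RNA, which would raise them by about the same factor, stays open: over the 21 of these probe sets with a mean of at least 8, from 13 genes, changes differed by more than their errors (Q = 845), but the SD between gene means was 2.90, 1.96 or 1.41 times that within genes (mean SD, root mean variance or pooled by degrees of freedom), since the avenin-like b probe sets alone had an SD of 0.80. With the level of the spiked poly-A controls as a covariate, the median was 1.23 (SE of the members' mean 0.18), against 0.91 without it. These controls read lower in after-ripened seeds, while among dormant arrays the members' mean was highest (8.82) where the controls read highest (6.44). With such values the covariate raises the change, and its slope rests on 6 arrays, so this says little about RNA amount. Over 15 plain _at probe sets the median was 0.91 (SE of the members' mean 0.16). The rise was thus not confined to probe sets with another suffix. For prolamins alone the median was 0.61 over 8 plain _at probe sets (SE of the members' mean 0.14) against 0.98 over all 17. A plain suffix does not show that a probe set detects only 1 member, so cross-hybridisation within gene families stays open. Also open is whether these transcripts were more oxidised or more abundant after storage, since no array of unselected mRNA was used here, and whether the contrast of room temperature with frozen storage, rather than dormancy, may lie behind it. Reading the planned prolamin result as a change in oxidation during after-ripening therefore stays a hypothesis.

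Unnamed probe sets may extend this pattern. Probe sets sharing a cluster number with a named prolamin or inhibitor probe set but lacking a readable name numbered 19, in 3 clusters. Their median log2 change was 0.72, above the central 95% of 10000 random sets matched on mean signal (-0.10 to 0.07), and 8 were higher and 0 lower in limma's fit (18 of the 19 had a change above 0). Probe sets of the same cluster can share sequence, so they are not independent evidence. The random sets were drawn without regard to clusters, so their range may be too narrow for 19 probe sets in 3 clusters.

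Higher calls carried a suffix for probe sets shared between transcripts in 140 of 405 cases (34.6%) and lower calls in 69 of 246 (28.0%), against 20.8% of all probe sets. The odds ratio of higher against lower calls was 1.35 (95% interval 0.947 to 1.95, Fisher's exact test, two-sided, p = 0.0999), so a difference between the directions was neither shown nor excluded.

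The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. For probe sets, the real groups gave 651 and the highest of the other splits 0, so 1 of 10 splits reached the real count. For the lists fixed before the data were examined, the real groups gave 1 list and the highest of the other splits 3, and 5 of 10 splits gave at least as many as the real groups.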
